A study of Drosophila melanogaster with 3 samples.

How the data were processed

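The assay was ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin. Per the labels' protocols, abdominal cuticles of 50 Drosophila melanogaster pupae per replicate were dissected at 38 to 45 h after puparium formation, internal organs were removed, and the epidermal cells left on the cuticle were processed by an Omni-ATAC procedure with a lysis buffer containing 0.1% of the detergent IGEPAL. The labels name 3 replicates of 1 wild-type group, and they give no sex. A single merged peak list was used here, with 34718 peaks on the arms 2L, 2R, 3L, 3R, 4 and X.

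Per the submitters' processing notes, BWA, SAMtools, Picard and MACS2 were used with the dm6 genome build. Versions, settings, the handling of duplicate reads and the way the 3 replicates were merged are not given in the sources used here. Each deposited peak has a start, an end, a summit and 4 values that the authors' peak caller assigned to it. The deposited fold enrichment is a linear ratio of the read pileup at the summit to the caller's local background. The −log10 p and −log10 q values in the deposited list belong to the same summit. The deposited score is a display value equal to the integer part of 10 times the −log10 q apart from rounding, and it was not used further. These values describe all replicates together, so replicate error could not be computed, no test between replicates was made, and every p-value below measures spread over windows, genes or random placements within this 1 list.

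Sequencing depth per replicate is unknown from the list. The whole-number pileup at each summit and its background were recovered by solving the caller's definitions, fold enrichment as (pileup + 1) / (background + 1) and −log10 p as a Poisson tail. A whole pileup was found for all 34718 peaks, within a tolerance of 0.002 on the −log10 p scale. The largest residual was 0.00014, against a step of at least 0.0125 between neighbouring whole numbers. The background had a floor of 57.2 overlapping reads, which was the value at 26.4% of the peaks. If reads were extended to the shortest peak length, 150 bp, this floor corresponds to 0.381 read starts per bp. At the median pileup of 149, the 95% Poisson interval runs from 126 to 175 and covers counting error only. In 18828 simulated summits the pileup was recovered in 100% of cases.

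Positions were compared with a RefSeq gene table for the same Release 6 assembly, and coordinates are 1-based. The table gives the span of each gene but no strand, transcription start, exon or UTR, and no genome sequence was used here. The planned promoter class (within 500 bp of a transcription start) was therefore replaced by a gene-end class, meaning a summit within 500 bp of either end of an annotated gene, coding or not. All other summits are called distal, and they were divided into gene interior and intergenic. A gene-end peak may thus lie at a 3' end, and an internal promoter counts as distal. Exons, introns and UTRs were not separated, and the planned search for 18 sequence motifs was not run.

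Each protein-coding gene was given a domain, the sequence nearer to one of its ends than to an end of any other protein-coding gene, and distal summits were counted in that domain. Of 24 gene lists fixed before the data were examined, 5 were defined by symbol patterns and the others by names. All names were found among 13922 protein-coding genes, 4 of them through current symbols. A list's share of genes with a gene-end summit, and its distal summits per 10 kb of domain, were compared with 100000 random lists matched on decile of domain length. These tests were two-sided, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. The smallest unadjusted p that they can give is 2e-05. Alternatives for the lists used 10000 random lists.

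Summit density on X and on the autosome arms was compared in 200 kb windows by a two-sided permutation test with 100000 resamples. Summit classes were compared with 1000 circular shifts of all summits along each arm, which keep the spacing of the peaks. Height and width of gene-end and distal peaks were compared as differences of medians in 1 Mb windows holding at least 5 peaks of each class, with a sign-flip permutation test of 100000 resamples. Distances between neighbouring distal summits were compared with 1000 random placements on the sequence beyond 500 bp of gene ends. The smallest p is 0.002 for shifts and placements, and 1e-05 for the window tests.

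Genes named in the text follow a rule written before the data were examined. It takes 18 fixed loci, the 10 genes with the most distal summits, and the 5 gene-end and 5 distal peaks of highest fold enrichment. In each list it takes the 2 members with the most distal summits, the 2 with the highest fold enrichment at a gene end, and the first 2 in alphabetical order without a gene-end peak. Other Hox genes, dpp, shg and the features named in the closing part were chosen after their values were seen. The stretch between Ptp4E and ovo was not part of that rule either.

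The tests were tried on simulated data. Among lists of 20 unchanged genes, 5% were called for gene ends and 4% for distal density at an unadjusted p under 0.05. With up to 20 percentage points added to the gene-end share, 22% of lists of 10 genes were called. With up to 25 points added, 56% of lists of 20 and 100% of lists of 100 were called. With the distal density doubled, the calls were 49%, 67% and 93% for those sizes. For the X comparison, 6.5% of random sets of 117 autosome windows were called, and 99% after 20% of their summits were removed. The sign-flip test called 5% of unchanged sets of 130 windows and 99% of sets shifted by 0.4 SD. Circular shifts and spacing tests called 0% of 40 unchanged sets each and 100% of 40 changed sets each. The unchanged lists and sets were drawn as each test assumes, with windows permuted for the X comparison. Their rates therefore cannot show errors that arise when neighbouring windows or summits are not independent.

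The alternatives fixed beforehand were a stricter set of peaks (the 17359 with the highest −log10 q), merging of peaks under 100 bp apart, gene-end distances of 250 and 1000 bp, ends of protein-coding genes only, any base of a peak in place of its summit, and analysis without X. For the lists they were unmatched random lists, 1 member per cluster of members under 50 kb apart, domains limited to 20 kb from a gene end, and omission of the member with the most distal summits. Of these, the 250 bp distance was not planned for distal density, nor the omission of a member for gene ends, and both uses were added after seeing the data. Another 6 alternatives were new at that point. They were the recovered pileup as the height, with all peaks and with the stricter set, and summits per protein-coding gene of each window. The others were placements that keep the local number of summits and gene ends over 1000 bp from the ends of other genes. Such gene ends are called isolated, although they may lie inside another gene. The last was density over the part of the domain beyond 500 bp of any gene end. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.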

Results

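Open chromatin was profiled in the abdominal epidermis of wild-type Drosophila melanogaster pupae, the cell sheet that secretes the adult abdominal cuticle, at 38 to 45 h after puparium formation. The stated aim was to map open chromatin across the genome. There were 3 replicates of 50 pupae each, all of 1 group, and the values came as 1 peak list for all replicates together. No value below therefore has a replicate error.

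The list held 34718 peaks on dm6. They covered 15.5 Mb, or 11.6% of the 134 Mb span of the 6 annotated arms, and their median width was 357 bp (interquartile range 226 to 574 bp). The median fold enrichment was 2.01 (interquartile range 1.73 to 2.40, highest 4.45), and 86.6% of the peaks had a q-value under 1e-05. Behind these ratios lay a median of 149 overlapping reads at the summit, ranging from 79 to 277, over a local background with a median of 68.1 reads.

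The gene-end peak of highest fold enrichment was at tup, which encodes a LIM-homeodomain factor (2L:18880714–18882037, fold enrichment 4.45, 104 bp from the annotated end of the gene). It was followed by peaks at Awh (3L:3845486–3846662, 4.28), Gsc (2L:594562–595550, 4.21), otp (2R:20903325–20904013, 4.21) and the Hox gene pb (3R:6741407–6742421, 4.19). All 5 are homeodomain genes, which was not tested for enrichment, and all 5 peaks had a background between 57.2 and 59.9 reads, at or near its floor. Of the 5 highest distal peaks, 4 lay inside genes and 1 was intergenic. The highest was inside dnc, which encodes a cAMP phosphodiesterase (X:3255844–3256289, 4.45). The next were inside Hs3st-A, a heparan sulfate sulfotransferase gene (2R:18745676–18746598, 4.36), inside the LIM-homeodomain gene ap, 518 bp from its annotated end (2R:5726286–5727644, 4.35) and inside CG9932 (2L:13043957–13044582, 4.26). The intergenic one lay 3368 bp from the nearest end of a protein-coding gene, that of CG30371 (2R:8271978–8273174, 4.23).

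The homeobox gene hth had the most distal peaks, with 75 distal summits in a domain of 185 kb and no peak at either end of the gene. It was followed by olf413 with 55, CG43658 with 53, CG42238 and the transcription factor gene fru with 51 each, and ed, which encodes an immunoglobulin-family adhesion protein, with 50. The leucine-rich repeat gene kek5 had 47, CG42747 had 45, the Wnt receptor gene fz2 had 43 and CG43759 had 42. Of 13922 protein-coding genes, 8441 (60.6%) had no distal summit in their domain, and the mean was 1.71. The 621 genes with 10 or more, 4.46% of the genes, held 44.1% of all distal summits and 20.8% of the domain sequence. Their density was 3.78 per 10 kb against 1.78 over all domains, but these genes were selected on the count itself.

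The first comparison asked where open chromatin lay relative to genes. Gene ends held 10855 summits, or 31.3%, against 18.0% ± 0.497 (SD over 1000 circular shifts), a ratio of 1.74. Gene interiors away from the ends held 17981 summits (51.8% against 56.4% ± 0.724, ratio 0.919), and sequence outside genes held 5882 (16.9% against 25.6% ± 0.976, ratio 0.661). Adjusted p was 0.002 for each class, the smallest that the shifts can give. The shifts ran over whole arms, so they also moved summits into stretches with few summits and few genes. How much of these ratios comes from such stretches was not tested. A summit lay within 500 bp of an end of 9127 protein-coding genes, or 65.6%.

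Gene-end peaks were also higher than distal ones. The median fold enrichment was 2.24 at gene ends and 1.92 at distal sites, and the mean difference over 130 windows of 1 Mb was 0.360 ± 0.199 (SD), positive in 129 of them (sign-flip permutation p = 1e-05). The recovered pileup differed in the same direction, with medians of 159 and 144 reads and gene-end peaks higher in 121 of the 130 windows (permutation p = 1e-05 by the same test). Gene-end peaks were wider as well, with a median of 384 bp against 348 bp and a mean window difference of 55.8 bp ± 98.1 (SD, 101 of 130 windows, permutation p = 1e-05). Among the 17359 peaks with the highest −log10 q the difference in width was −3.35 bp (permutation p = 0.726) and that in fold enrichment 0.198. The difference in pileup there was 2.69 reads in place of 18.5, with medians of 179 and 178 and gene-end peaks higher in 67 of 127 windows (permutation p = 0.0172). The local background was lower at gene ends. Its mean window difference was −4.15 reads with all peaks (higher at gene ends in 19 of 130 windows) and −5.38 among the 17359 (18 of 127). Part of the difference in fold enrichment with all peaks thus lies in the background. The 17359 peaks were selected on −log10 q, which at a given pileup rises as the background falls. Gene-end peaks can therefore enter that set with fewer reads, and it cannot divide the difference between pileup and background.

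Distal summits lay closer together than random placement gave. The median distance between neighbours was 1981 bp for 23863 distal summits, against 3703 bp ± 26.1 (SD) when they were placed at random on each arm (p = 0.002 by permutation of positions, the smallest that 1000 placements can give). When the number of distal summits in each 200 kb window was kept, random placement gave 2967 bp ± 20.9 (permutation p = 0.002).

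The arms differed in density. Peaks numbered 281 per Mb on 2L, 271 on 3L, 259 on 3R, 255 on 2R, 234 on X and 205 on 4. In 200 kb windows, X held 47.0 ± 20.6 summits (SD, n = 117 windows) and the autosome arms 2L, 2R, 3L and 3R held 53.2 ± 27.4 (n = 543), a difference of −6.19 (two-sided permutation p = 0.0214). The test treats windows as exchangeable, although windows with few summits lie in runs, so its p-values may be too small. The difference was −12.6 in windows with at least 10 protein-coding genes (permutation p = 1e-05). It was lost among the 17359 peaks with the highest −log10 q (26.3 on X and 26.0 on the autosomes, permutation p = 0.839), and summits per protein-coding gene of each window were 2.89 and 3.01 (permutation p = 0.542). At a given pileup the −log10 q rises as the background falls, and the mean background was 66.8 reads on X against 73.5 on the autosomes. The stricter set can therefore favour X peaks and cannot decide whether the difference in density holds.

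The next comparison asked which groups of genes carried open chromatin at their ends. Of the 24 lists, 7 lay above random lists matched on domain length, and 4 lay below. Groups that build and pattern the epidermis were among those above. Of 19 genes for signalling ligands and receptors, 18 had a gene-end summit (94.7% against 63.2% in random lists, adjusted permutation p = 0.0185), with wg at a fold enrichment of 3.97 and bnl, which encodes an FGF ligand, at 3.87. The exception was spi, an EGF receptor ligand gene, which had 8 distal summits. Of 19 chitin synthesis and apical matrix genes, 18 had one (94.7% against 65.1%, adjusted permutation p = 0.0225), led by the chitin deacetylase gene serp at 3.54 and by knk, needed for chitin organisation, at 3.37. The chitinase gene Cht5 had none. All 13 planar polarity genes had a gene-end summit (100% against 65.6%, adjusted permutation p = 0.026), among them the receptor gene fz at 3.54 and the atypical cadherin gene stan at 3.37. Of 20 body wall patterning transcription factor genes, 18 had one (90.0% against 63.2%, adjusted permutation p = 0.0362). In that list tup and the Iroquois gene caup were highest, at 4.45 and 4.18, while hth and mirr had none.

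Genes used in many cell types were also represented. All 18 cell cycle genes had a gene-end summit (100% against 67.5%, adjusted permutation p = 0.0103), with the cyclin genes CycA at 3.68 and CycD at 3.16. Of 92 ribosomal protein genes, 81 had one (88.0% against 64.7%, adjusted permutation p = 0.00024), with RpL21 at 3.51. RpL10Aa and RpL12 had none. Of 48 proteasome genes, 31 had one (64.6% against 65.2%, adjusted permutation p = 1). The ribosomal protein and proteasome lists were drawn by symbol pattern, and whether every member is used in many cell types was not checked. They also hold related genes such as Prosalpha1R and Prosbeta5R1, which had no gene-end peak, and RpS28-like, which had one at 3.38. Among markers of other tissues, 19 of 21 muscle genes had a gene-end summit (90.5% against 64.8%, adjusted permutation p = 0.0362), a call lost within 250 bp (0.154), within 1000 bp (0.0989) and without how, the member with the most distal summits (0.0557). Taking 1 member per 50 kb cluster kept the same 21 genes (unadjusted permutation p = 0.0146), and only the adjustment over all lists moved their p to 0.0501. The myoblast fusion gene sns reached 2.92 and the actin gene Act57B 2.86, while the flight muscle actin gene Act88F and the calponin-family gene Mp20 had none.

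Of the 4 lists below random lists, 3 hold genes of cell types other than the epidermis. Of 179 chemosensory receptor genes, 41 had a gene-end summit (22.9% against 66.8%, adjusted permutation p = 0.00024), with Or46a at 3.33 and Or67a at 3.23 and none at Gr10a and Gr10b. Of 28 gut enzyme genes, 9 had one (32.1% against 65.6%, adjusted permutation p = 0.0056), where the neighbours LManI and LManII were both at 3.28 and both amylase genes, Amy-d and Amy-p, had none. Of 21 germline genes, 8 had one (38.1% against 65.4%, adjusted permutation p = 0.0407), with piwi and orb at 2.75 and none at Mst84Da and Mst84Db. Structural cuticle protein genes, which the epidermis uses, made up the other list, with 69 of 127 (54.3% against 66.5%, adjusted permutation p = 0.0189). That call was lost with 1 member per cluster (−7.22 points, adjusted permutation p = 0.501) and within 1000 bp (−6.73 points, 0.179). Cpr76Bc reached 3.30 and Cpr57A 3.27 in that list, and Acp1 and Ccp84Aa had none.

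The other 12 lists besides the proteasome genes did not pass the test with all peaks and gene ends of 500 bp. All 8 Hox genes had a gene-end summit, against 62.7% in random lists (adjusted p = 0.0844 by permutation). The counts were 17 of 19 ecdysone response genes (adjusted permutation p = 0.0564), 20 of 23 epithelial junction and polarity genes (0.0583), 8 of 19 neuronal genes (0.148), 11 of 13 trichome effectors (0.275) and 10 of 12 pigmentation genes (0.437). For marker lists of other cells they were 8 of 15 for fat body, 6 of 11 for hemocytes, 4 of 7 for oenocytes, 6 of 8 for trachea and 9 of 12 for sense organ precursors, and 6 of 8 cell death genes had one, with adjusted p between 0.626 and 1 in permutation tests. The number of lists called was 5 with 1 member per 50 kb cluster, 7 within 1000 bp and 14 among the 17359 peaks with the highest −log10 q, and the calls that held under all 7 alternatives run were those of signalling genes and chemosensory receptors.

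Some lists gained a call under an alternative. Hox genes passed in 3 of the 7 (adjusted permutation p from 0.0164 to 0.0248), junction and polarity genes in 3 (0.0144 to 0.0367) and ecdysone response genes in 2 (0.0164 and 0.0363), all above random lists. The ecdysone list fell from 25.2 to 7.24 points with only isolated gene ends (8 of 15 genes, adjusted permutation p = 0.838). Neuronal genes lay below random lists among the 17359 peaks (adjusted permutation p = 0.0185). The use of isolated gene ends, over 1000 bp from ends of other genes, was an alternative chosen after seeing the data. Trichome effectors and pigmentation genes passed there (adjusted permutation p = 0.0288 each), and cuticle protein genes lay above random lists by 13.5 points (0.0281). The same setting left 5 planar polarity (29.5 points, adjusted permutation p = 0.618), 7 cell cycle (15.2, 0.793), 18 ribosomal protein (18.6, 0.307), 5 germline (−24.1, 0.76) and 16 gut enzyme genes (−26.8, 0.0585), with no call for any of them. With 1 member per cluster no call was left for 18 body wall transcription factors, at 25.7 points against 26.8 with every member (adjusted permutation p = 0.0875), or for 17 chitin genes, at 28.7 against 29.7 (0.0501). The same held for 12 gut enzyme genes, at −32.6 against −33.5 points (adjusted permutation p = 0.0916), and 16 germline genes, at −22.4 against −27.3 (0.216). Within 1000 bp all 13 planar polarity and all 18 cell cycle genes still had a summit, the most possible, against 76.1% and 77.9% in random lists (adjusted permutation p = 0.125 and 0.0619), so the measure was saturated there. Germline genes lost theirs within 1000 bp (−13.6 points, adjusted permutation p = 0.377), among the 17359 peaks (−23.8, 0.072) and without the member with the most distal summits (−25.6, 0.0641). Planar polarity was at 31.7 points within 250 bp (adjusted permutation p = 0.0716), and body wall transcription factors at 24.4 against unmatched random lists (0.0593).

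**Figure D1:**
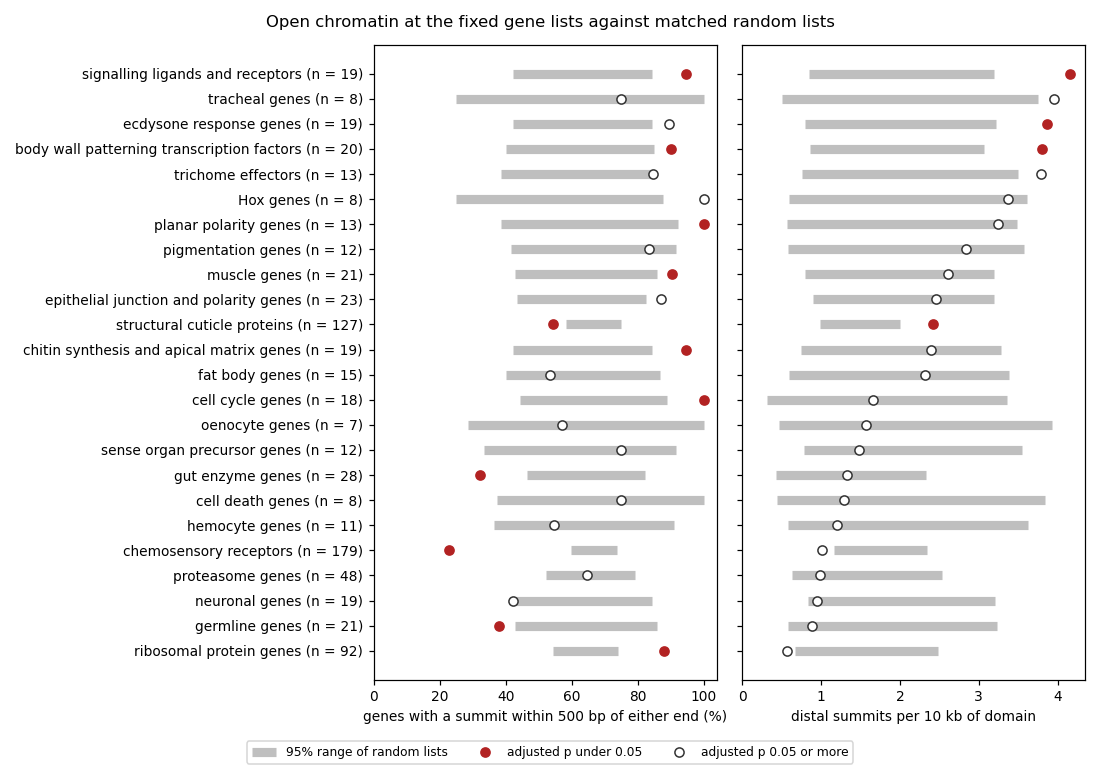
For each of the 24 gene lists (n genes in brackets), points give the percentage of genes with a summit within 500 bp of either end (left) and the number of distal summits per 10 kb of domain (right), and grey bars give the 95% range of matched random lists. Filled points have an adjusted p under 0.05, 11 lists on the left and 4 on the right, with chemosensory receptors lowest on the left (22.9%) and signalling genes highest on the right (4.16).

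Distal density separated the same 24 lists differently. With all peaks and whole domains it was above random in 4 lists and below it in 0. The domains of signalling ligand and receptor genes held 4.16 distal summits per 10 kb against 2.05 in matched random lists, a ratio of 2.02 (adjusted permutation p = 0.00192). Within that list fz2 had 43 and vn, an EGF receptor ligand gene, 24. Body wall patterning transcription factor genes had 3.80 per 10 kb (ratio 1.91, adjusted permutation p = 0.00408), led by hth with 75 and the POU-domain gene vvl with 41. Ecdysone response genes had 3.86 (ratio 1.91, adjusted permutation p = 0.00828), led by the nuclear receptor gene Eip75B with 38 and the ETS factor gene Eip74EF with 32. Structural cuticle protein genes had 2.42 against 1.49 (ratio 1.63, adjusted permutation p = 0.00416), led by Cpr50Ca with 10 and TwdlT with 8. With domains limited to 20 kb from a gene end the ratios of these 4 lists were 1.90, 1.62, 1.79 and 1.62 in the same order. All 4 calls held there (adjusted permutation p = 0.0016, 0.00864, 0.006 and 0.0016).

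The remaining lists did not pass there. The highest ratios among them were 1.90 for tracheal genes (adjusted p = 0.0825 by permutation), where knrl had 29 and kni 17, and 1.76 for trichome effectors (0.0686), where dsx-c73A had 21 and mey 18. That list passed against random lists of genes with an isolated end (ratio 1.88, adjusted permutation p = 0.0394), an alternative chosen after seeing the data. Hox genes had a ratio of 1.63 (0.241), planar polarity genes 1.62 (0.241) and pigmentation genes 1.39 (0.492). Lists below 1 included ribosomal protein genes at 0.363 (0.0825), neuronal genes at 0.461 (0.210), germline genes at 0.479 (0.334) and chemosensory receptors at 0.563 (0.0825). Muscle genes were at 1.30 (0.492), with 23 distal summits at how and 22 at Msp300. Among the other lists the ratio was 1.20 for fat body genes, 1.17 for chitin and for junction genes, 1.02 for gut enzymes, 0.972 for cell cycle genes and 0.743 for oenocyte genes. It was 0.681 for sense organ precursor genes, 0.647 for proteasome genes, 0.622 for cell death genes and 0.584 for hemocyte genes, and the adjusted p of these 10 lists lay between 0.492 and 0.99 in permutation tests. Without the member with the most distal summits the ratio was 0.413 for cell cycle genes, where E2f1 had 15 of 20, 0.222 for oenocyte genes, where svp had 15 of 20, and 0.361 for cell death genes, where hid had 13 of 26. Germline genes were at 0.829 with domains limited to 20 kb from a gene end (adjusted permutation p = 0.804). Cell cycle genes were at 1.47 and fat body genes at 0.734 among the 17359 peaks, and ribosomal protein genes at 0.235 beyond 1000 bp and 0.586 beyond 250 bp. With domains limited to 20 kb, chemosensory receptors (ratio 0.523, adjusted permutation p = 0.0016) and neuronal genes (0.439, 0.0272) lay below random lists, as ribosomal protein genes did among the 17359 peaks with the highest −log10 q (0.153, 0.0352). The call for the signalling list was lost among the 17359 peaks with the highest −log10 q (ratio 1.68, adjusted permutation p = 0.159). The call for the cuticle proteins was lost there (1.30, 0.413), with gene ends of 1000 bp (1.52, 0.0858), with unmatched random lists (1.32, 0.238) and with 1 member per cluster (1.56, 0.104).

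The fixed loci were described by their peaks alone. The gene ovo, whose shavenbaby product directs the formation of trichomes, lies on X at 5048273–5070929. It had 1 gene-end peak of fold enrichment 1.95 and 18 distal summits in its domain, 13 at lower coordinates than the gene and 5 inside it. This was 3.78 distal summits per 10 kb, against 1.85 over all genes in the same decile of domain length. That decile also holds long domains with few summits, such as that of AGO3 (252 kb, 0.238 per 10 kb), and the decile below it had 2.38. The 5 distal peaks of highest fold enrichment were X:5055111–5055697 (2.71), X:5066524–5067841 (2.70) and X:5068203–5068994 (2.48), all inside ovo, and X:5046342–5046643 (2.50) and X:5046793–5047442 (2.35), both within 1725 bp of its annotated end and inside the non-coding gene lncRNA:CR44833. From the end of Ptp4E at 4955916 to the start of ovo lay 92.4 kb with 50 summits, or 5.41 per 10 kb against 2.59 over all arms. That average includes 23.8 Mb in stretches over 50 kb without a summit. Of these peaks, that of highest fold enrichment was at X:4971891–4972838 (3.40), nearer to the small gene CG15468 than to ovo. Almost all of this stretch lies within lncRNA:CR44833 (4956646–5063868).

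**Figure D2:**
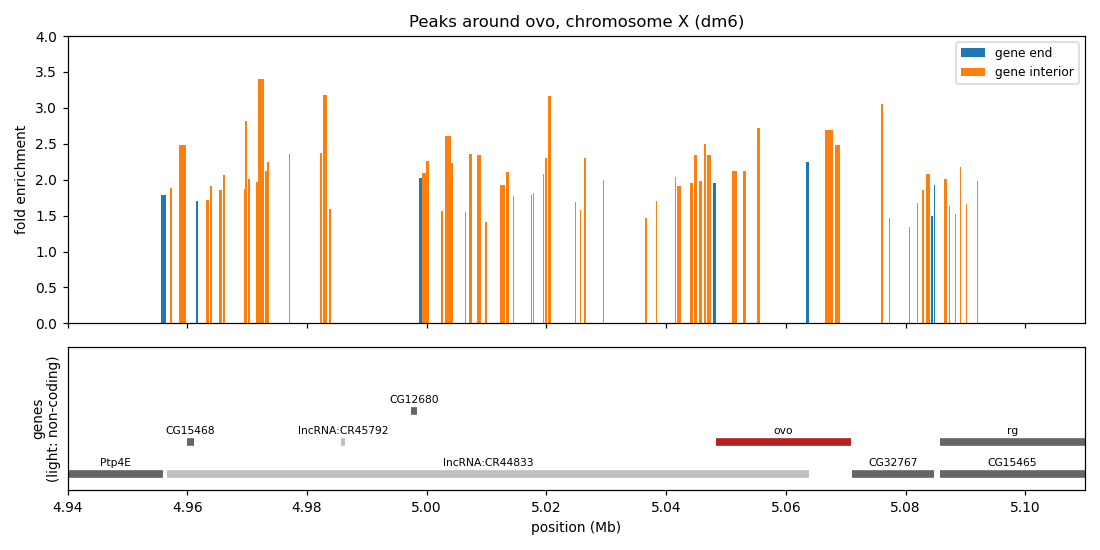
Peaks on X (dm6) from Ptp4E to the start of rg and CG15465, drawn as bars from start to end, with the fold enrichment as height and the class of the summit as colour, above the spans of annotated genes (ovo in red, other coding genes dark grey, non-coding genes light grey). The 92.4 kb between Ptp4E and ovo hold 50 summits, and the highest peak there reaches 3.40.

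Among the pigmentation loci, the transcription factor genes bab1 (3L:1036369–1101089) and bab2 (3L:1140429–1177276) had 32 and 22 distal summits and gene-end peaks of 2.64 and 2.48. Their domains were 84.4 and 62.7 kb long, and their distal densities 3.79 and 3.51 per 10 kb against 1.85 in their decile of domain length and 2.38 in the decile below. Among the enzyme genes, whose domains are shorter, ple, the tyrosine hydroxylase gene (3L:6713356–6719525), had 3 distal summits and a gene-end peak of 3.91. The beta-alanyl-dopamine synthase gene e (3R:21229839–21237177) had 2 in a domain of 10.2 kb and a gene-end peak of 2.48. Their densities, 2.31 and 1.96 per 10 kb, compare with 2.38 and 2.07 in their deciles. The dopa decarboxylase gene Ddc (2L:19116483–19120306) had 0 distal summits in 3.47 kb and a gene-end peak of 2.76. The gene y (X:356509–361245) had 2 distal summits and a gene-end peak of 2.44, and t (X:9217655–9223257) had 1 distal summit and no gene-end peak.

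Of the Hox genes that specify abdominal segments, Ubx (3R:16656623–16734426) had 40 distal summits and a gene-end peak of 3.68, Abd-B (3R:16927212–16972236) had 21 and 2.22, and abd-A (3R:16807214–16830049) had 7 and 3.72. Hox genes of head and thorax were also open, with gene-end peaks of 4.19 at pb, 3.93 at lab, 3.90 at Dfd, 3.85 at Scr and 3.14 at Antp, and Antp had 40 distal summits. Among trichome effectors, sha (2R:11324314–11336463) had 5 distal summits, all inside the gene, and a gene-end peak of 1.88. The gene mwh (3L:1200786–1232700) had a gene-end peak of 2.47 and 9 summits inside its span, with 0 distal summits in its own domain. The zona pellucida protein genes neo and dy had gene-end peaks of 2.80 and 2.68, and m and sn had none.

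The epidermal transcription factor gene grh (2R:17801132–17842820) had 18 distal summits and a gene-end peak of 2.34. The signalling genes wg (2L:7307159–7316265) and hh (3R:23128169–23141906) had 14 and 5 distal summits and gene-end peaks of 3.97 and 2.68. The ecdysone receptor gene EcR (2R:6087873–6169087) had 38 summits inside its span, 14 distal summits in its domain and a gene-end peak of 2.29, and the ecdysone-induced gene br (X:1575132–1664869) had 24 and 2.94. Among genes outside the fixed loci, the BMP ligand gene dpp had 21 distal summits and a gene-end peak of 2.04, and the E-cadherin gene shg had 8 and 2.52. Fold enrichment compares a summit with its own surroundings, and its median was 2.06 for peaks with 0 other summits within 5 kb and 1.78 for those with 8 or more, while the median pileup was 119 and 169 reads. Fold enrichment at crowded loci therefore cannot be set directly against that at isolated peaks.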

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

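The alternatives on pileup, summits per gene, local placement, isolated gene ends and trimmed domains were chosen after seeing the data, as were density beyond 250 bp and gene ends without the member with the most distal peaks. The classes of summit position, the difference in fold enrichment between gene-end and distal peaks, and the spacing of distal summits kept their direction and their side of the threshold under every alternative run on them. All alternatives for the classes used shifts over whole arms. Among the 17359 peaks the difference in fold enrichment came with a lower background at gene ends (−5.38 reads) and a pileup difference of 2.69 reads. Selection on −log10 q can itself change both values, so this set cannot divide the difference between them. With the stricter set of 17359 peaks the difference in density between X and the autosomes turned to 0.288 summits per window (permutation p = 0.839) and the difference in width to −3.35 bp (p = 0.726). Ranking by −log10 q can favour X there, since its peaks had a lower background. Dividing by protein-coding genes left an X difference of −0.124 summits per gene (permutation p = 0.542). The number of lists called for gene ends, 11, became 7 within 1000 bp and 5 with 1 member per cluster. With only isolated gene ends, over 1000 bp from ends of other genes, the cuticle proteins turned from −12.2 to 13.5 points. Over 24 lists and 7 alternatives, gene-end results kept direction and call in 130 cases, gained a call in 11, lost it in 22 and turned in 5. Besides the cuticle proteins, the lists that turned were cell death genes within 1000 bp (−0.0338 points) and proteasome genes among the 17359 peaks (4.57), within 250 bp (2.06) and with 1 member per cluster (1.87). Distal density, over 24 lists and 9 alternatives, kept both in 194 cases, gained a call in 4, lost it in 5 and crossed a ratio of 1 in 13. Among the 17359 peaks these were cell cycle (1.47), chitin (0.937), muscle (0.953), fat body (0.734) and gut enzyme genes (0.728). Without the member with the most distal peaks they were fat body (0.842) and gut enzyme genes (0.787), and with unmatched random lists gut enzyme genes (0.719). With domains beyond 500 bp of any gene end cell cycle genes crossed (1.07), and beyond 250 bp cell cycle (1.16) and gut enzyme genes (0.863). With only genes that had an isolated end, fat body (0.919) and gut enzyme genes (0.872) crossed. Apart from that of the cuticle proteins, no gene-end or density value that turned was called before or after. Calls for gene ends that held under all 7 were those of signalling genes and chemosensory receptors, and the 2 distal density calls that held under all 9 were those of body wall transcription factors and ecdysone response genes. The cause of these changes was not tested, apart from that weighed for the cuticle proteins. The alternatives planned for motif content were not run, since no genome sequence was used here. No paired analysis was possible because the list holds 1 group and no values per replicate. Lists of about 10 genes limit what can be seen, since 22% of those with a raised gene-end share were called in simulation.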

Other observations

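The tests in this part were chosen after the data had been seen, except some of those on structural cuticle protein genes. For these genes, the tests with every member, with 1 member per cluster and within 1000 bp were fixed before the data were examined. Of 290 tRNA genes, 207 (71.4%) had a summit within 500 bp of an end, against 23.8% ± 3.76 (SD) under circular shifts (adjusted permutation p = 0.00371). As for the summit classes, circular shifts also move summits into stretches with few summits and few genes. Of the 220 tRNA genes over 500 bp from coding gene ends, 152 (69.1%) had one, against 23.7% ± 4.09 (adjusted permutation p = 0.00371). Of 503 antisense RNA genes, 302 (60.0%) had one against 35.0% ± 2.30 (adjusted permutation p = 0.00371), but of the 133 over 500 bp from coding gene ends 60 (45.1%) had one against 35.2% ± 4.22 (adjusted permutation p = 0.0552). Among lncRNA genes the share was 47.0% against 33.3% ± 1.36 (adjusted permutation p = 0.00371). The snoRNA genes (22.7% against 24.3%, adjusted permutation p = 0.755) and miRNA genes (28.1% against 24.1%, adjusted p = 0.321) did not pass the test. All pseudogenes together did not pass either (65 of 245, 26.5% against 32.5%, adjusted permutation p = 0.112), while those over 500 bp from coding gene ends lay below, with 14 of 107 (13.1% against 32.9% ± 5.26, adjusted permutation p = 0.00371).

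Among domains of at least 20 kb, that of CG3777 had the highest density, with 7.52 distal summits per 10 kb. It was followed by the nuclear receptor gene Eip78C with 7.47, the bHLH gene crp with 7.35, CG32639 with 7.34 and the polarity gene baz with 6.93. At the other extreme, 208 stretches over 50 kb held no summit, 23.8 Mb in all. One of them, 2L:21401561–21553465, spans 111 protein-coding genes of the histone cluster, and another, X:21739046–22258531, spans 519 kb. How reads from repeated copies were placed is not given in the sources used here. Other such stretches held gustatory receptor genes of the Gr22 group (2L:1748639–1875320), ionotropic receptor genes of the Ir7 group (X:7769604–7888770) and the Mst84D genes (3R:7358422–7436075).

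Rankings by fold enrichment and by pileup gave different peaks. Of the 1000 highest peaks by each measure, 181 were shared, and Spearman's rho across all peaks was 0.659, where peaks are not independent. X held 23.6% of the highest by fold enrichment, 7.3% of the highest by pileup and 15.8% of all peaks. The highest pileup, 277 reads, was inside Eip75B (3L:17964699–17965473), at a fold enrichment of 1.89 because its background was 146 reads. The next highest distal peak by pileup lay 642 bp from Rh5 (2L:12010052–12011194, 272 reads), followed by one inside Hr3 (2R:10213826–10214495, 269 reads).

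Peaks on X had a mean fold enrichment of 2.22 against 2.09 on the autosome arms, and a mean background of 66.8 against 73.5 reads, a difference of −6.69. Less open chromatin near X peaks is argued against, since at equal summed peak signal within 5 kb the background still differed by −4.86 (permutation p = 1e-05), although open sites too weak to be called were not counted. The ratio of X to autosomes for the upper quartile of gene-end pileup was 0.984 (95% bootstrap interval 0.957 to 1.01). An equal mix of males and females with equally open copies, 0.75 copies of X, would give 0.831 below a ceiling of 300 reads and 0.841 with the lowest ceiling that the data allow, which argues against that explanation. A smaller share of males, more open X copies in males through dosage compensation, and differences in mappability may each contribute and stay open, as the labels give no sex.

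Summit pileups filled a narrow range, with a 99th percentile of 239 and only 75 peaks above 250. A candidate explanation is that 1 read start was kept per base and strand, which would limit a pileup of 150 bp reads to 300, and the largest pileup, 277, lay at 92.3% of that limit. If so, the ratio of the largest pileup to the background floor would be 12.1 in place of 4.84, and that of the median pileup 3.25 in place of 2.60. How duplicates were treated is not given in the sources used here, and weak enrichment without such a limit stays open. No biological explanation was tested.

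Structural cuticle protein genes lay below random lists for gene ends and above them for distal density. A candidate explanation is that peaks at ends of neighbouring genes add to the random lists more than to the cuticle genes, which lie in clusters of their own kind. With only isolated gene ends, 45 of 92 cuticle genes (48.9%) had a summit against 35.4% in random lists. The difference of 13.5 points (adjusted permutation p = 0.0281) is what that explanation predicts. A gene was kept here if at least 1 of its ends lay over 1000 bp from ends of other genes. Random lists were not matched on the number of such ends, so the setting does not single out that explanation. The 127 genes form 49 clusters, and with 1 member of each the difference at gene ends was −7.22 in place of −12.2 points (adjusted permutation p = 0.501) and the density ratio 1.56 in place of 1.63 (0.104), while within 1000 bp they were −6.73 points (0.179) and 1.52 (0.0858). With domains beyond 500 bp of any gene end the density call held at 1.86 (adjusted permutation p = 0.0024), and whether cuticle genes active at this stage differ from the others was not tested.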
